A study of Homo sapiens with 6 samples.

How the data were processed

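RNA of ES2 cells was sequenced in 6 libraries, 3 transfected with a control siRNA and 3 with UAP1 siRNAs, with RNA taken 48 hours after transfection and the medium changed after 6 hours. Per the labels' protocols, libraries were made by poly(A) enrichment or depletion of ribosomal RNA, without stating which, although the molecule is given as polyA RNA, and were sequenced on an Illumina NovaSeq instrument. Samples were grouped by their titles, which name the siRNA and a replicate number. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

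The authors deposited a table of raw counts per gene for 58735 genes, and the whole-number values summed to between 21267240 and 25972582 per library. They also deposited a table of FPKM (counts scaled by gene length and library total), whose implied denominators were 0.988 to 1.03 times the library totals. The submitters' processing notes name the genome build GRCh38.p12 and DESeq2. The aligner, the counter and any use of strand are not given in the sources used here, so that overlapping genes, antisense genes and near-identical copies are reported as uncertain. Gene coordinates are those of the deposited table, 1-based on GRCh38, and 58724 of its 58735 genes had the same start and end in GENCODE release 29. Replicates of a group were compared by a chi-square test over genes with at least 20 counts, and every pair differed by far more than counting noise (chi-square per degree of freedom 23.9 to 41.3), so that none was counted as a repeat of another. Mitochondrial transcripts took 4.23% to 6.02% of the counts.

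The main test was edgeR 4.0.16 (in R 4.3.3): TMM scaling, filterByExpr with its minimum count of 10, which kept 15768 genes, a quasi-likelihood fit on the group and Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05. CPM are counts scaled to TMM-adjusted library totals, given as mean ± SD over 3 libraries. Gene lists (36, written with the design) were tested with camera of limma 3.58.1 with a preset correlation of 0.01. It was run on the filtered, TMM-scaled counts with their fitted dispersions, where at least 5 members were tested, adjusted over lists. Log CPM with a prior count of 2 served for the principal components, the pairing check and the values of single pairs. Members past the threshold were also counted with p-values adjusted over the list alone. Lists of fewer tested members (leukocyte, erythroid and keratinocyte markers) are given as values. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance in 1 direction, were alternatives.

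The groups share replicate numbers in the titles, and a fit with the number as a block was an alternative. Whether the numbers pair the samples was checked, before the calls of the fits were compared, by correlating each library's deviations from its group mean over tested genes, and pairing was accepted if every pair's correlation passed 0.1. Libraries with the same number correlated at 0.552, 0.454 and 0.584, and all those with different numbers at between -0.434 and -0.0893. Deviations cancel out within a group, so positive values for the same number make the others negative on average. The negative values are therefore no separate evidence of pairing. The libraries' names also share a code within each number, whose meaning is not stated. The numbers were taken to pair the samples, and blocked values are given beside the results they change.

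The genes to name were set by a rule. It takes UAP1 and every tested hexosamine list member, and the 10 largest rises and 10 largest falls among protein-coding genes with adjusted p under 0.05, mean CPM of at least 5 and no overlap of the groups. It adds the 5 risen and 5 fallen genes of smallest p under the same conditions, up to 4 called members per list (with the 2 uncalled members of smallest p where fewer than 2 were called), and the most abundant marker of each other cell type. The rule was applied to both the fit without and the fit with pairs, and the text names some of the list members it gave. Some genes that the rule gave are not reported here, in the text or the figures. Groups, the main test, the lists, the rule and the first set of alternatives were fixed before the data were examined.

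These alternatives were RLE scaling, library totals without TMM, no filter beyond 1 count, mean CPM of at least 5, protein-coding genes alone, the replicate block, leaving out each library in turn, DESeq2 1.42.0, limma-voom, and limma on log2(FPKM + 1) or log2(FPKM + 0.1) with a mean FPKM of at least 1 or no filter, where fold changes are on the log2(value + pseudocount) scale. DESeq2 gave no adjusted p for 43187 genes without and 46624 with the block, and these were left out. Alternatives within the blocked fit (other tools and scalings, offsets for gene length and GC, leaving out each pair, leaving out genes with a shifted 3' UTR word, and other list tests) were chosen after seeing the data. All data in the counts table were used.

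The 3' UTR search took each gene's longest annotated 3' UTR among basic protein-coding transcripts of GENCODE release 29 (18776 genes with one). Other 3' UTRs of a gene were not searched. It kept 10247 genes of at least 5 CPM with a fold change from the blocked fit. Each of 16318 words of 7 bases that occurred in at least 30 genes was scored by a z value against words of the same base composition, with a bound of 4.5. The siRNA sequences were not used. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for it, and matplotlib 3.10.9 for the figures.

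The fits were tested on simulated counts for 15385 genes, drawn from the means and library sizes of these libraries for siUAP1 against control. The differences between pairs and the spread were those of the blocked fit, so the simulation favours that fit by design. Changed genes were taken from those of at least 5 CPM, and a single draw was made. The fit without pairs recovered 23.9%, 79.1% and 98.5% of genes changed 1.5-fold, 2-fold and 4-fold, and the blocked fit 95.5%, 100% and 100%, with 0 and 12 false calls among 134 and 209. With no gene changed, each made 0 calls. A list of 40 genes shifted 1.3-fold was called by camera in both fits and 0 of 33 unshifted lists were (15362 genes). Simulated genes were drawn independently, whereas members of real lists moved together, with an estimated correlation of 0.815 in the cholesterol list without pairs. The simulation therefore does not show how often the preset correlation gives false calls in such lists. With an estimated correlation the shifted list was called without pairs (adjusted p = 0.000917) and missed with the block (0.0565), so that 0 calls there with the block do not show that no list moved. In the 3' UTR search, a single shuffle of fold changes over 10247 genes gave z values between -3.92 and 4.29. It breaks any movement of genes together. A word whose 1019 genes were shifted by -0.15 was ranked 1 (z = -20.6). That signal was stronger than any found in the data, so recovery of weaker shifts was not tested.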

Results

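ES2 cells are a human ovarian cancer line, labelled in the series as high-grade serous carcinoma. They were transfected with either a control siRNA or siRNAs against UAP1, the enzyme that joins N-acetylglucosamine phosphate to UTP to make UDP-N-acetylglucosamine, the sugar donor for N-glycans, hyaluronan and O-GlcNAc. A small interfering RNA (siRNA) is a short duplex that directs the cell to destroy matching mRNA. The labels list 2 UAP1 siRNAs and 1 control siRNA and do not say whether the UAP1 siRNAs were pooled or which library received which. RNA was taken 48 hours after transfection. Gene counts were given for 3 control and 3 siUAP1 libraries, which held 21267240, 25054159 and 24842621 counts (control replicates 1 to 3) and 23727266, 25972582 and 25909989 counts (siUAP1 replicates 1 to 3). Of 58735 genes in the table, 15768 had enough counts to be tested. Libraries with the same replicate number lay together on the first and second principal components, which took 39% and 24.1% of the variance, and the groups separated on the third, with 18.7%.

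**Figure D1:**
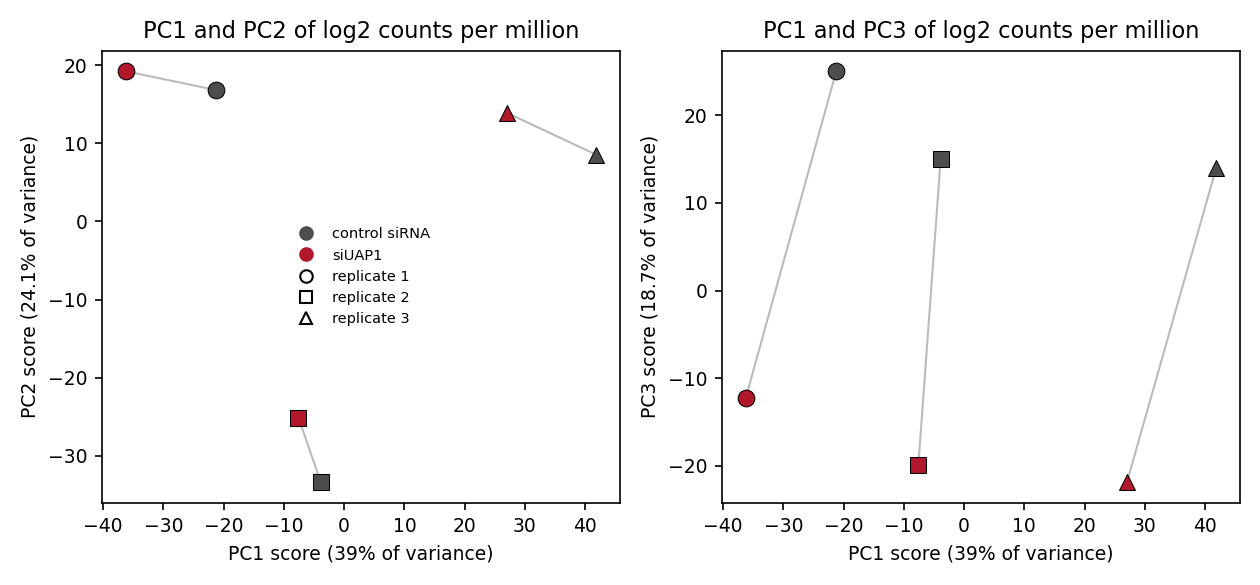
Scores of the 6 libraries on principal components 1 and 2 (left) and 1 and 3 (right) of log2 CPM; the axes give each component's share of the variance, colour gives the group, symbol the replicate number, and a line joins libraries with the same number. Libraries with the same number are neighbours on components 1 and 2 (39% and 24.1%), and component 3 (18.7%) has all control libraries above all siUAP1 libraries.

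The comparison asked how the transcriptome of ES2 cells differed with UAP1 knocked down. UAP1 itself (ENSG00000117143, GRCh38 chromosome 1, 162561506 to 162599842, plus strand) fell from 382.2 ± 54.12 CPM (counts scaled to library size, SD, n = 3) in control to 23.43 ± 1.702 CPM (SD, n = 3) in siUAP1 libraries. Its counts were 7341, 9081 and 10848 in the control libraries and 521, 608 and 642 in the siUAP1 libraries. The log2 fold change was -4.03 (SE 0.136, edgeR adjusted p = 6.12e-06), a 16.3-fold fall. Compared within replicate numbers, UAP1 was 93.7%, 93.5% and 94.3% lower. Its paralogue UAP1L1 was at 8.85 CPM in control and 9.04 CPM in siUAP1 libraries, with a log2 fold change of 0.03 (SE 0.165, adjusted p = 0.996).

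**Figure D2:**
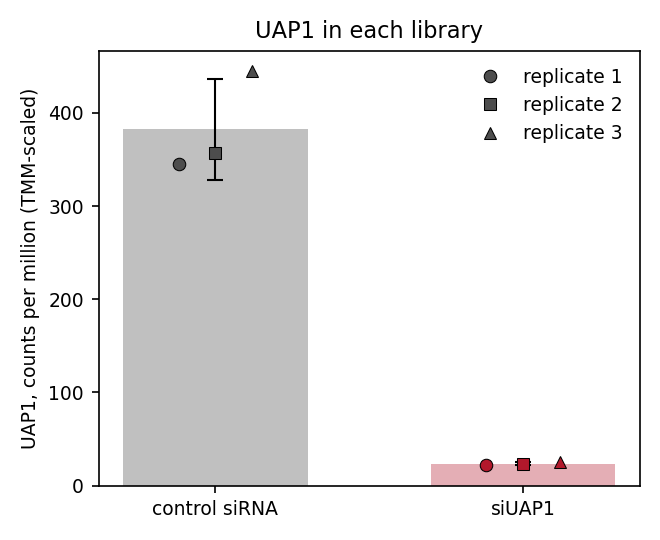
UAP1 level in each library in CPM (TMM-scaled, linear axis from 0); bars are group means, error bars are SDs over 3 libraries and symbols give the replicate number. Control libraries lie at 345.3, 357 and 444.4 CPM and siUAP1 libraries at 21.81, 23.27 and 25.2 CPM.

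Besides UAP1, the genes that differed most clearly between the groups included MMP1, which encodes interstitial collagenase, the acyltransferase gene LCLAT1, the matrix genes TGFBI and TINAGL1, and the ETS transcription factor gene ETV5. MMP1 was among the abundant transcripts and fell from 7112 ± 63.75 to 3860 ± 77.77 CPM (SD, n = 3; log2 fold change -0.88, SE 0.0833, edgeR adjusted p = 0.0137). TINAGL1 rose 2.27-fold (log2 1.19, SE 0.135, adjusted p = 0.0369) and TGFBI, a secreted matrix protein, rose 2.24-fold (log2 1.17, SE 0.148, adjusted p = 0.0453). LCLAT1 fell from 22.96 ± 1.816 to 8.234 ± 1.319 CPM (log2 -1.48, adjusted p = 0.0253). In all, 17 genes changed in this fit, which used the groups alone: 5 rose (TINAGL1, TGFBI, ALDH3B1, WDR18 and UACA) and 12 fell. The others that fell were KHSRP, an RNA-binding protein of AU-rich elements (-0.88), the secreted proteoglycan gene ESM1 (-0.87), ETV5 (-0.86), THUMPD1 (-0.97), the oligosaccharyltransferase subunit gene MAGT1 (-0.78), the semaphorin receptor gene PLXNA2 (-0.74), FAM32A (-0.71) and the non-coding AL596244.1 (-1.64) and LINC02376 (-0.88), all with adjusted p between 0.00518 and 0.0483. These non-coding genes lie outside the naming rule and were chosen after their values were seen. Overlapping genes in the annotation make the counts of ETV5 (with DGKG, 11.7 CPM against 91.4) and MMP1 (with WTAPP1 on the opposite strand, 1.91 CPM) slightly uncertain. At an unadjusted p under 0.05 there were 1125 genes. Leaving out 1 library at a time left 2 genes without control replicate 1, 2 or 3 or siUAP1 replicate 1 (UAP1 and AL596244.1), 1 without siUAP1 replicate 2 (UAP1) and 3 without siUAP1 replicate 3 (UAP1, AL596244.1 and MMP1).

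With the replicate number as a block, so that siUAP1 was compared with control within each of the 3 pairs, 2556 genes changed: 1430 rose and 1126 fell, and all 17 genes were among them. Most of these differences were small. The median size was 0.294 on the log2 scale, and 94 genes rose and 27 fell by at least 2-fold. Of the 2556, 2511 had the same sign in all 3 pairs. They were called from these same pairs, so that agreement is no independent check. Without pair 3 the count was 1195, and without pair 1 or 2 it was 2204 or 1987. The 2 groups' CPM did not overlap in 1963 genes (12.4% of those tested). Chance gives 10% if all libraries are exchangeable, an assumption that leaves out the pairs. From here on, rose and fell, members' fold changes and list medians refer to the fit with pairs (3 pairs, edgeR), unless the fit without pairs is named.

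The largest rise among protein-coding genes of at least 5 CPM whose groups did not overlap was that of the histone gene HIST1H2BK (log2 fold change 1.55, SE 0.152), which shares near-identical sequence with other histone genes, so that its counts are uncertain. MMP2, which encodes gelatinase A, rose from 87.09 to 238.6 CPM (1.44, SE 0.0512, adjusted p = 3.19e-16). The other large rises included those of LMLN (1.31), clusterin (CLU, 1.25), the vitamin D receptor gene VDR (1.22), the transcription factor gene ATOH8 (1.22), TINAGL1 (1.18), TGFBI (1.18) and the export pump gene ABCC3 (1.16). Under the same limits, the largest falls after UAP1 were those of BCL2A1, an anti-apoptotic BCL2 relative (-1.67, SE 0.113, adjusted p = 1.01e-10), and LCLAT1 (-1.48, SE 0.0998). AKT1S1, a subunit of mTORC1 (-1.14), the recycling-endosome GTPase gene RAB4A (-1.13), the potassium channel gene KCNU1 (-1.09), SKI, a repressor of TGF-beta signalling (-1.08), TTLL11 (-1.03), CD274, which encodes the immune checkpoint ligand PD-L1 (-0.98), and the keratin-associated KRTAP2-3 (-0.97) followed. KRTAP2-3 has a near-identical neighbour and AKT1S1 overlaps TBC1D17 on the opposite strand (28.3 CPM against 43.5), so both are uncertain. Among the smallest p-values were also the rises of ITGB5 (0.72), NUCKS1 (0.74) and ITGA5 (0.66).

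**Figure D3:**
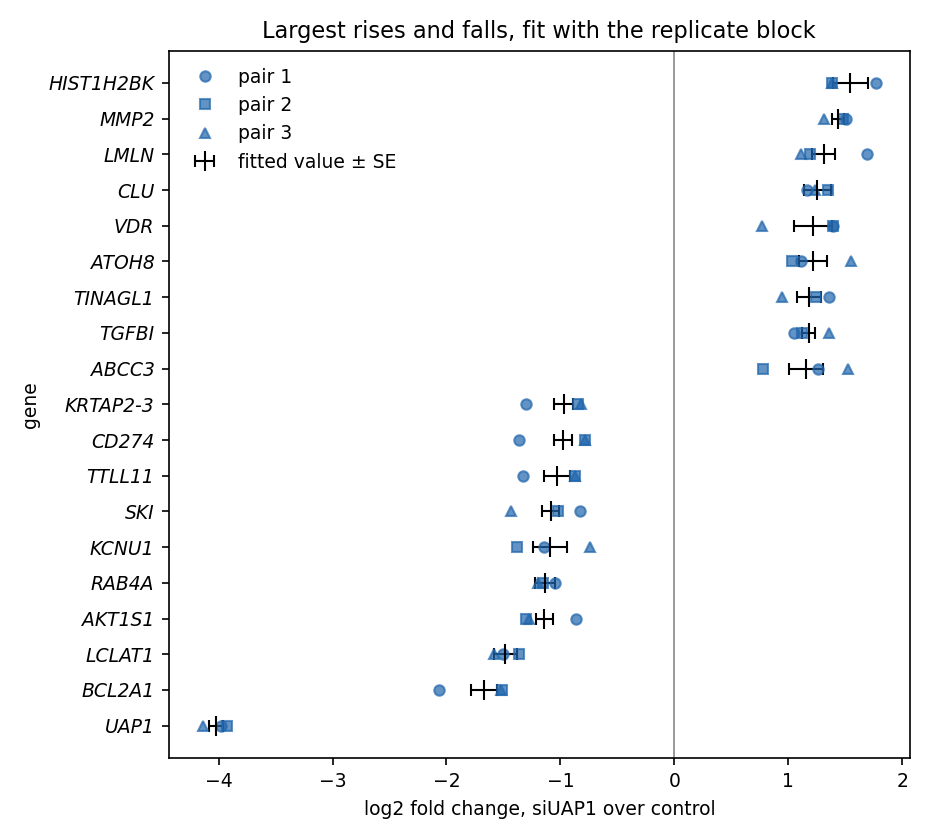
Log2 fold change of siUAP1 over control (horizontal axis) for genes named among the largest rises and falls in the fit with the replicate block; black marks are fitted values with their standard errors and blue symbols the 3 pairs. Each gene drawn lies on the same side of 0 in all 3 pairs, from UAP1 at -4.02 to HIST1H2BK at 1.55.

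A search of annotated 3' UTRs, described with the closing observations, found 5 words of 7 bases whose genes lay lower in siUAP1 libraries and 3 whose genes lay higher, here called downward and upward words. They are marked for named genes that rose or fell. A downward word stood in the 3' UTR of LCLAT1, ETV5, MAGT1, FAM32A, THUMPD1, SKI, AKT1S1, RAB4A and KRTAP2-3, and an upward word in that of WDR18, LMLN, NUCKS1 and LCLAT1. Neither kind stood in the longest annotated 3' UTR, the one searched, of UAP1, MMP1, KHSRP, BCL2A1, ESM1, MMP2, TGFBI, TINAGL1, UACA or ALDH3B1.

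Among 36 gene lists fixed before the data were examined, 33 had at least 5 tested members, and camera with a preset correlation called 22 of them in the fit without pairs, 17 higher and 5 lower. The camera p-values given for lists are from that fit unless the pairs are named. With an estimated correlation camera called 0 lists, the lowest adjusted p being 0.111, and with the pairs the preset test called 25. The same fit without pairs called 5 single members over all lists: UAP1, MAGT1, MMP1, TGFBI and ETV5. Overlaps with other tested genes in the annotation also make uncertain the counts of CCND1, CMAS, FANCA, FOXM1, GALNT7, GALNT10, GINS2, GNE, GNPDA2, IRF1, KRT7, MT-ND4L, NANS, NPC1, NUF2, PGM3, PRDX1, PTX3, RAD54L and TP53INP2.

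The hexosamine pathway and O-GlcNAc cycling list was lower, with 5 of 18 members falling and 13 not called (5 and 13 adjusted over the list alone), and its camera adjusted p was 7.55e-08, or adjusted p = 0.111 with an estimated correlation. The camera call rested on UAP1: over the other 17 members camera gave adjusted p = 0.231, or 0.116 with the pairs. Fry called those 17 lower with the pairs (adjusted p = 0.0205, median -0.0186) and not without them (0.385). The smaller falls included those of GNPDA1, a glucosamine-6-phosphate deaminase (-0.32, SE 0.0495, adjusted p = 3.35e-05), the O-GlcNAc hydrolase gene OGA (-0.21, SE 0.0487) and the acetyltransferase gene GNPNAT1 (-0.19, SE 0.0502), and the 3' UTRs of GNPDA1 and OGA hold a downward word. GNPNAT1 was not called without pair 1 (adjusted p = 0.0554) or pair 3 (0.0892), and OGA not without pair 3 (0.115). Not called were GFPT1, the pathway's entry enzyme (0.03, SE 0.0463, adjusted p = 0.77), GFPT2 (-0.09), PGM3 (-0.06), the O-GlcNAc transferase gene OGT (0.03, SE 0.0519, adjusted p = 0.743) and UAP1L1 (0.03). Values of the remaining 8 (GNE, CMAS, GNPDA2, NANS, NAGK, EOGT, AMDHD2 and RENBP) ran from -0.15 for NAGK to 0.13 for GNE, and none was called.

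Genes of N-glycan assembly did not move as a list, whereas lists of Golgi branching, mucin-type O-glycosylation and glycosaminoglycan synthesis lay above other genes. Of 42 N-glycan assembly and transfer genes, 2 rose and 1 fell (the same counts adjusted over the list alone, and 0 and 1 in the fit without pairs). MAGT1 was the gene that fell, and camera gave adjusted p = 0.515; the median was 0.00133 while the mean was -0.0245. In Golgi N-glycan branching and capping, 6 of 23 rose and 1 fell (9 and 1 adjusted over the list alone), among them the galactosyltransferase gene B4GALT1 (0.42, SE 0.0511, with an upward word) and MAN2A2 (0.31, with an upward word, not called without pair 3), with camera adjusted p = 0.0386, or adjusted p = 0.533 with an estimated correlation. In mucin-type O-glycosylation, 5 of 17 rose and 1 fell (5 and 1 adjusted over the list alone): GALNT10 (0.65, SE 0.0583), GALNT7 (0.39) and GALNT2 (0.37) rose and GALNT1 fell (-0.39), each of these a transferase that starts O-glycans, with camera adjusted p = 0.00877, or adjusted p = 0.317 with an estimated correlation. GALNT7 and GALNT2 hold an upward word and GALNT1 a downward word. In hyaluronan and glycosaminoglycan synthesis, 13 of 31 rose and 1 fell (13 and 2 adjusted over the list alone), including EXTL3 (0.42, with an upward word), NDST1 (0.37) and B3GAT3 (0.30) of heparan sulfate synthesis, with camera adjusted p = 0.000708, or adjusted p = 0.221 with an estimated correlation. In the fit without pairs, the counts adjusted over the list alone were 1 and 0 for Golgi branching, 2 and 1 for O-glycosylation and 3 and 0 for glycosaminoglycan synthesis. The Golgi list's call ended without control replicate 2 (adjusted p = 0.254), control replicate 3 (0.135) or siUAP1 replicate 1 (0.335) and with protein-coding genes alone (0.0506), and that of O-glycosylation without control replicate 3 (0.0615) or siUAP1 replicate 1 (0.124). With the pairs, the Golgi call also ended without genes holding a shifted word (median 0.12 to 0.107, adjusted p = 0.176).

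Genes of protein folding in the endoplasmic reticulum went both ways. Of 36 ER chaperone and ER-associated degradation genes, 6 rose and 6 fell (6 and 7 adjusted over the list alone, and 0 and 1 in the fit without pairs), with camera adjusted p = 0.605. SELENOS fell (-0.68, SE 0.074), as did CRELD2 (-0.41) and MANF (-0.34), while the co-chaperone gene DNAJB9 rose (0.55, SE 0.111, with words of both kinds); CRELD2 overlaps ALG12 and DNAJB9 overlaps PNPLA8 and THAP5 on opposite strands, so both are uncertain. Of 41 integrated stress response genes (targets of ATF4 and CHOP), 17 rose and 1 fell (23 and 1 adjusted over the list alone, and 0 and 0 in the fit without pairs). The growth factor gene GDF15 (0.92, SE 0.145), SESN2 (0.53, with an upward word), the amino acid transporter gene SLC7A5 (0.42) and CEBPB (0.30) were among those that rose. Camera gave adjusted p = 0.000173 for this list, or adjusted p = 0.533 with an estimated correlation, and its call ended without control replicate 2 (0.0662) or siUAP1 replicate 1 (0.0598).

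Lists of extracellular matrix genes and of integrins and growth factor receptors lay above other genes. Of 43 collagen and matrix genes, 26 rose, 2 fell and 15 were not called (28 and 3 adjusted over the list alone, and 11 and 2 in the fit without pairs). The median was 0.342 on the log2 scale (0.35, 0.34 and 0.35 in pairs 1 to 3). MMP2 rose (1.44), as did TGFBI (1.18) and the metalloproteinase inhibitor gene TIMP3 (1.09, SE 0.0534, with an upward word), while MMP1 fell (-0.88). Camera gave adjusted p = 4.6e-10, or adjusted p = 0.378 with an estimated correlation. Of 45 integrin and growth factor receptor genes, 22 rose, 2 fell and 21 were not called (24 and 3 adjusted over the list alone, and 8 and 0 in the fit without pairs), including ITGB5 (0.72, SE 0.0472), ITGA5 (0.66), the semaphorin and VEGF coreceptor gene NRP2 (0.70) and ITGA1 (0.64). ITGA1 holds an upward word, NRP2 holds words of both kinds, and ITGA1 overlaps PELO on the same strand, so it is uncertain. This list had adjusted p = 1.95e-08, or adjusted p = 0.378 with an estimated correlation. Neither the matrix nor the integrin list lost its call when any 1 library was left out, although the matrix median of 0.338 in the fit without pairs became 0.181 without control replicate 3 and 0.53 without siUAP1 replicate 3.

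Of 23 TGF-beta targets, 12 rose and 3 fell (15 and 3 adjusted over the list alone, and 3 and 2 in the fit without pairs). TGFBI (1.18, SE 0.056) was among those that rose, whereas SKI (-1.08) and CTGF (-0.61, SE 0.0495), a matricellular growth factor, fell. Of 25 YAP and TEAD targets, 12 rose and 2 fell (14 and 2 adjusted over the list alone, and 0 and 1 in the fit without pairs). The members that fell were CTGF and ANKRD1 (-0.40, SE 0.0462), both widely used readouts of YAP activity, while TGFB2 (0.65) and FJX1 (0.47) rose. Camera adjusted p was 0.0014 for TGF-beta targets and 0.00765 for YAP targets, or adjusted p = 0.533 and 0.378 with an estimated correlation. Without siUAP1 replicate 1 both calls ended (adjusted p = 0.172 and 0.122), and without control replicate 2 that of YAP targets did (0.0904). With the pairs, the YAP call also ended without genes holding a shifted word (median 0.197 to 0.0586, adjusted p = 0.0679). Lists of epithelial and of mesenchymal markers both lay above other genes. Of 28 epithelial markers only 10 had enough counts to be tested. Of the 10 tested, 4 rose and 0 fell (4 and 0 adjusted over the list alone, and 0 and 0 in the fit without pairs). Those that rose were the keratin genes KRT8 (0.78, SE 0.0555, with an upward word), KRT7 (0.58) and KRT18 (0.50), and CLDN4. KRT8 and KRT18 overlap on opposite strands and are uncertain. Of 19 mesenchymal markers 6 rose and 2 fell (6 and 2 adjusted over the list alone, and 1 and 0 in the fit without pairs), with MMP2, the fibroblast activation protein gene FAP (0.98, SE 0.113), SNAI2 (0.50) and TPM1 (0.42, with an upward word) among those that rose. The epithelial list had camera adjusted p = 0.00703 and the mesenchymal list 0.0411, or adjusted p = 0.244 and 0.681 with an estimated correlation. The mesenchymal call ended without control replicate 3 (0.626), siUAP1 replicate 1 (0.53, with a median of -0.0233) or siUAP1 replicate 2 (0.0712), and with library totals (0.0521), a mean CPM of at least 5 (0.057) or protein-coding genes alone (0.063), and CLDN4 was not called without pair 3.

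**Figure D4:**
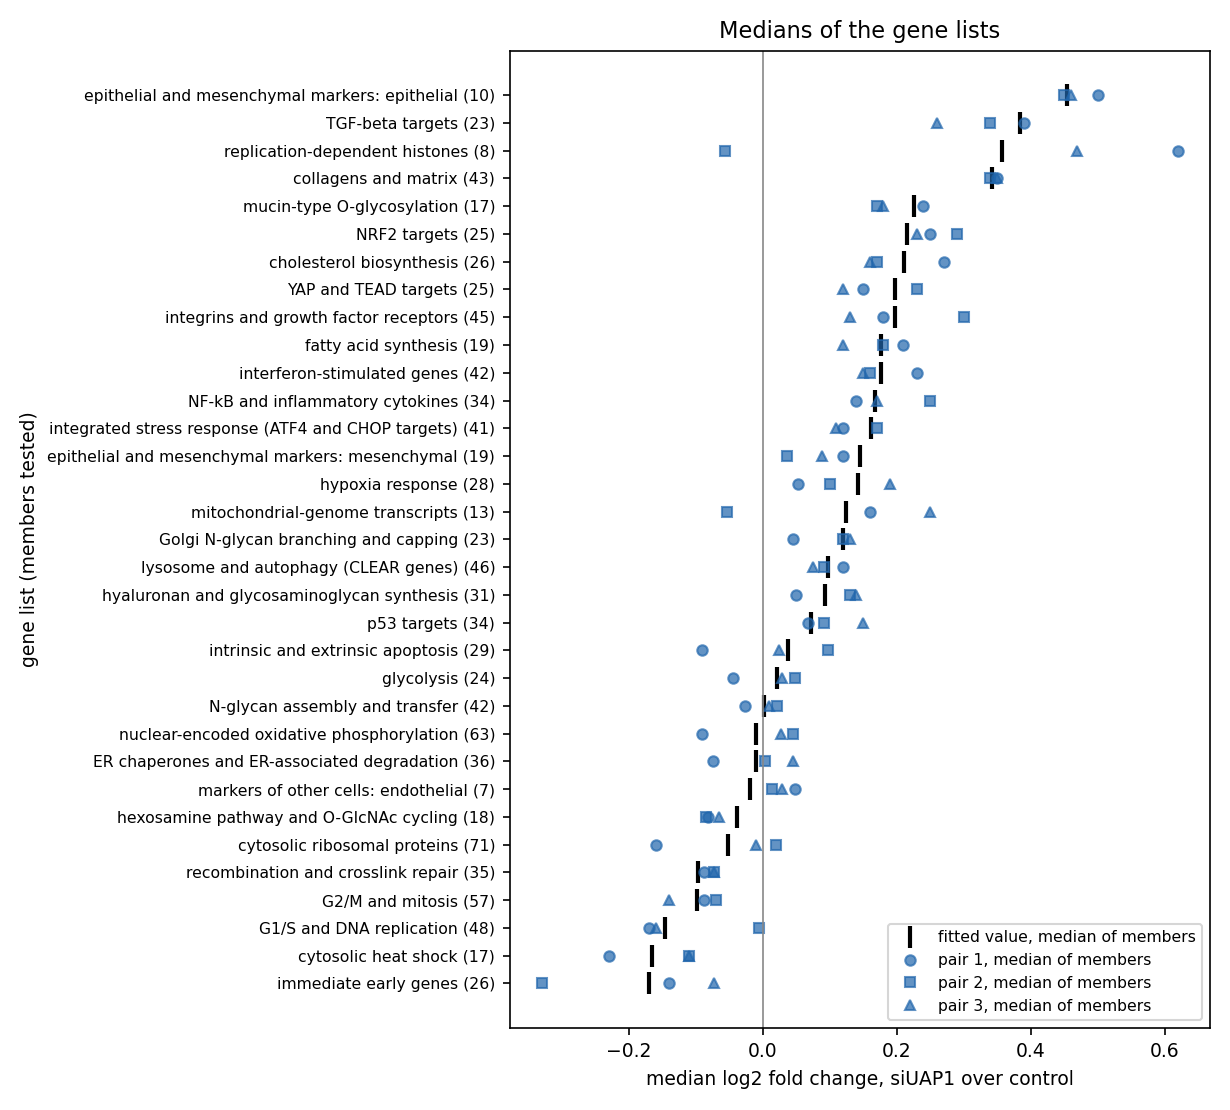
Median log2 fold change of siUAP1 over control (horizontal axis) over the tested members of each of 33 gene lists, with the number of members in brackets; black marks are medians of the fitted values with the replicate block and blue symbols medians in the 3 pairs. The collagen and matrix list lies at 0.35, 0.34 and 0.35 in the 3 pairs, and immediate early genes lie below 0 in each.

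Lists of immediate early genes and of cell division genes lay below other genes, with most of their members not called. Of 26 immediate early genes, 1 rose and 9 fell (2 and 10 adjusted over the list alone, and 0 and 6 in the fit without pairs), with camera adjusted p = 1.92e-06, or adjusted p = 0.317 with an estimated correlation. ETV5 (-0.86), EGR1 (-0.82, SE 0.0971), DUSP6 (-0.55) and SPRY2 (-0.53), all of which respond to ERK signalling, fell, and the 3' UTRs of ETV5 and EGR1 hold a downward word and that of SPRY2 an upward word. Of 48 genes of G1/S and DNA replication, 1 rose and 12 fell (1 and 13 adjusted over the list alone), such as MCM10 (-0.36) and GINS2 (-0.35, with a downward word), and CCND1, which encodes cyclin D1, was the gene that rose (0.24, SE 0.0466). MCM10 was not called without pair 1, and GINS2 and CCND1 not without pair 3. Of 57 genes of G2/M and mitosis, 1 rose and 14 fell (1 and 16 adjusted over the list alone), among them BUB3 (-0.32, SE 0.0478), NUF2 (-0.28), FOXM1 (-0.25) and CDK1 (-0.24, with a downward word). Of 35 genes of homologous recombination and crosslink repair, 0 rose and 4 fell, also adjusted over the list alone: RAD54L (-0.33), RAD51AP1 (-0.28), BLM (-0.27) and FANCA (-0.22). RAD54L and BLM were not called without pair 3 and FANCA not without pair 2. In the fit without pairs these 3 lists had 0 members past the threshold adjusted over the list alone. Camera adjusted p was 0.0014 for G1/S, 0.00242 for G2/M and 0.0298 for recombination, or adjusted p = 0.727, 0.731 and 0.681 with an estimated correlation. All 3 calls ended without siUAP1 replicate 1 (adjusted p = 0.795, 0.795 and 0.716), where the G1/S and G2/M medians were 0.0223 and 0.00185, and without control replicate 3 (0.135, 0.693 and 0.135), and that of recombination also ended without control replicate 2 (0.412) and with a mean CPM of at least 5 (0.057).

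Of 34 p53 targets, 8 rose and 4 fell (9 and 4 adjusted over the list alone, and 2 and 0 in the fit without pairs). GDF15 (0.92), TP53INP2 (0.70, SE 0.096, with an upward word) and SESN2 (0.53) rose, and camera gave adjusted p = 0.013, or adjusted p = 0.244 with an estimated correlation. With the pairs, that call ended without genes holding a shifted word (median 0.0728 to 0.045, adjusted p = 0.129). Of 29 apoptosis genes, 5 rose and 5 fell (5 and 6 adjusted over the list alone, and 0 and 2 in the fit without pairs), with camera adjusted p = 0.681 and opposite signs of the median (0.0373) and the test. The members that fell included the anti-apoptotic genes BCL2A1 (-1.67) and MCL1 (-0.45, SE 0.0455), MCL1 with words of both kinds, and those that rose included BID (0.34) and BIRC3 (0.31, with a downward word).

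Lists of lipid synthesis genes lay above other genes. Of 26 cholesterol biosynthesis genes, 16 rose and 0 fell (17 and 0 adjusted over the list alone), including INSIG1 (0.62, SE 0.0459), which retains the SREBP escort protein in the ER, and the enzyme genes HMGCS1 (0.52), MSMO1 (0.44, with an upward word) and IDI1 (0.40). Of 19 fatty acid synthesis genes, 10 rose and 0 fell (10 and 2 adjusted over the list alone), among them ME1 (0.47, SE 0.0529) and FASN, the fatty acid synthase gene (0.40). In the fit without pairs both lists had 0 members past the threshold adjusted over the list alone. Camera adjusted p was 9.29e-05 and 0.00202, or adjusted p = 0.681 and 0.533 with an estimated correlation, and without siUAP1 replicate 1 both calls ended (0.424, with a median of -0.0114, and 0.124). Of 25 NRF2 targets, 13 rose and 0 fell (17 and 0 adjusted over the list alone, and 2 and 0 in the fit without pairs), with ABCC3 (1.16, SE 0.145), NQO1 (0.56, with an upward word), ME1 (0.47) and PRDX1 (0.34, with an upward word) among them. This list had camera adjusted p = 1.56e-09, or adjusted p = 0.111 with an estimated correlation, and kept its call with any 1 library left out. Of 46 lysosome and autophagy genes, 14 rose and 4 fell (15 and 4 adjusted over the list alone, and 1 and 0 in the fit without pairs). The cholesterol transporter gene NPC1 rose (0.31, SE 0.0478, with an upward word) and the proton pump subunit gene ATP6V0D1 fell (-0.34), with camera adjusted p = 0.00673, or adjusted p = 0.533 with an estimated correlation. That call ended without control replicate 2 (0.194) or siUAP1 replicate 1 (0.124).

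Glycolysis, hypoxia and oxidative phosphorylation lists were not called. Of 24 glycolysis genes, 4 rose and 1 fell (6 and 2 adjusted over the list alone): LDHA rose (0.53, SE 0.0473, with an upward word) and HK2 fell (-0.37, SE 0.0519), with camera adjusted p = 0.644. Of 28 hypoxia response genes, 9 rose and 1 fell (12 and 1 adjusted over the list alone), the latter being ADAMTS1 (-0.67, SE 0.046), while LOXL2 rose (0.34), with camera adjusted p = 0.174. LOXL2 overlaps ENTPD4 on the same strand, so its counts are uncertain. Without control replicate 1 (0.0038) or siUAP1 replicate 2 (0.0483) the hypoxia list was called higher. Of 63 nuclear-encoded oxidative phosphorylation genes, 2 rose and 2 fell (0 and 2 adjusted over the list alone), including SDHA (-0.24, SE 0.0475, not called without pair 3), with camera adjusted p = 0.681, and the list was called lower without siUAP1 replicate 3 (0.0376). Of 8 replication-dependent histone genes, 1 rose, HIST1H2BK, and 0 fell (1 and 0 adjusted over the list alone, also in the fit without pairs), with camera adjusted p = 0.108. HIST1H2AG and HIST1H2AC were not called (-1.10 and 0.73), and without control replicate 1 (0.0286) or siUAP1 replicate 2 (0.00123) the list was called higher. With the pairs, camera gave the histone list adjusted p = 0.0703, and called it higher without genes holding a shifted word (6 members, median 0.398, adjusted p = 0.00554). In the fit without pairs the glycolysis, hypoxia and oxidative phosphorylation lists had 0 members past the threshold adjusted over the list alone.

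The pairs changed the call of 3 lists. Of 17 cytosolic heat shock genes, 1 rose and 11 fell (1 and 12 adjusted over the list alone), with camera adjusted p = 0.147 without and 0.000208 with the pairs, the latter becoming adjusted p = 0.478 with an estimated correlation. HSPA1B and HSPA1A (-0.34 and -0.32) share near-identical sequence and are uncertain, HSP90AB1 fell less (-0.16, SE 0.049), and HSPB1 was the member that rose (0.40, SE 0.0544, with an upward word). HSPA1B was not called without pair 1, HSPA1A not without pair 1 or 3, and HSP90AB1 not without pair 2 or 3. Of 13 mitochondrial-genome transcripts, 3 rose and 0 fell (7 and 0 adjusted over the list alone), MT-CYB (0.21), MT-ND4L (0.21) and MT-ND3 (0.19), with camera adjusted p = 0.174 without and 0.0112 with the pairs (adjusted p = 0.479 with an estimated correlation), and a median of -0.053 in pair 2. None of these 3 was called without pair 3, nor was MT-ND3 without pair 2. Of 71 cytosolic ribosomal protein genes, 1 rose and 2 fell (1 and 0 adjusted over the list alone), with camera adjusted p = 0.142 without and 0.0492 with the pairs (adjusted p = 0.811 with an estimated correlation). RPLP0 rose (0.27, SE 0.0484, with an upward word) and RPL14 (-0.17, with words of both kinds) and RPL29 (-0.15) fell, and processed pseudogenes make such counts uncertain. RPL14 was not called without pair 1 or 3, and RPL29 not with any pair left out. In the fit without pairs, these 3 lists had 0 members past the threshold adjusted over the list alone, and leaving out control replicate 2 called all 3 (heat shock 0.000196, mitochondrial 3.02e-06, ribosomal 0.000193). Without siUAP1 replicate 1 heat shock and mitochondrial transcripts were called (0.00053 and 0.00412), and without siUAP1 replicate 3 ribosomal proteins (2.58e-06). The medians without pairs reversed with other libraries left out, from -0.166 to 0.0465 for heat shock and 0.118 to -0.0287 for mitochondrial transcripts without control replicate 1 (-0.0194 without siUAP1 replicate 2), and from -0.0481 to 0.0453 for ribosomal proteins without control replicate 3 (0.0179 without siUAP1 replicate 1). With the pairs, the mitochondrial call ended without pair 3 (adjusted p = 0.316) and the ribosomal call without pair 1 (0.341, with a median of 0.00386) and with length and GC offsets (0.0649).

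Lists of inflammatory and of interferon-stimulated genes lay above other genes, with some members falling. Of 34 genes of NF-kB and inflammatory cytokines, 14 rose and 5 fell (17 and 5 adjusted over the list alone, and 2 and 1 in the fit without pairs). IL1B, the interleukin-1 beta gene (1.06, SE 0.0621, with an upward word), and the macrophage growth factor gene CSF1 (1.08, SE 0.0935) rose, while the chemokine gene CXCL5 (-0.74, SE 0.0573) and the pentraxin gene PTX3 (-0.79, SE 0.0693, with a downward word) fell. Camera gave adjusted p = 0.0386, or adjusted p = 0.731 with an estimated correlation. Of 42 interferon-stimulated genes, 14 rose and 1 fell (15 and 1 adjusted over the list alone, and 0 and 0 in the fit without pairs), including IRF1 (0.51, SE 0.0954), UBE2L6 (0.43) and HELZ2 (0.33), with camera adjusted p = 0.00602, or adjusted p = 0.533 with an estimated correlation. The inflammatory call ended without control replicate 2 (0.115), control replicate 3 (0.711), siUAP1 replicate 1 (0.795, with a median of -0.0251) or siUAP1 replicate 2 (0.117) and with a mean CPM of at least 5 (0.104) or protein-coding genes alone (0.0539), and the interferon call without control replicate 3 (0.135) or siUAP1 replicate 1 (0.141).

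Among markers of other cell types, few were measured at a testable level. Leukocyte markers summed to between 4.22 and 5.5 CPM per library, with CORO1A the most abundant (3.18 and 2.52 CPM in control and siUAP1 libraries, not called). CSF1R rose from 0.255 to 0.903 CPM (1.81, SE 0.471, adjusted p = 0.00881), was the leukocyte marker that rose of 2 tested (1 and 0 adjusted over the list alone, also in the fit without pairs), and was not called without pair 3; it overlaps the ribosomal pseudogene RPL7P1 (131 CPM) on the opposite strand and is uncertain. Endothelial markers summed to between 511 and 600 CPM, mostly from TIE1 (376.5 and 385.5 CPM) and CDH5, and 0 of 7 were called in either fit, over all genes or adjusted over the list alone, with camera adjusted p = 0.645 and a median of 0.0145 beside a mean of -0.0489 without the pairs. Keratinocyte markers summed to between 155 and 227 CPM, led by PERP (108.2 and 108.6 CPM), and of 3 tested TP63 fell (-0.42, SE 0.0678, with a downward word), also adjusted over the list alone, with 0 in the fit without pairs. Erythroid markers summed to at most 0.376 CPM, led by ALAS2, and 0 were tested.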

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

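The tests within the blocked fit, except the block itself, were chosen after the result was seen. UAP1 kept its direction and its call in every alternative (log2 fold change -3.84 with log2(FPKM + 1) to -4.10 without control replicate 1; leaving out 1 library gave -3.91 to -4.10). The count of 17 changed genes became 273 with no filter, 165 with DESeq2, 1 to 3 with 1 library left out, and 2, 3 and 1 with log2(FPKM + 1), log2(FPKM + 0.1) and unfiltered FPKM. With the replicate block, that is, within the pairs, it became 2556, and 2539 with RLE factors, 2587 with library totals, 2606 with length and GC offsets, 1311 with DESeq2, 2545 with limma-voom, 944 with FPKM, 1490 without genes holding a shifted word, and 2204, 1987 and 1195 without pair 1, 2 or 3. The causes of these differences were not tested. Of the 22 list calls, 8 to 22 were kept with 1 library left out, where 10 to 24 lists were called in all. Library totals kept 21, protein-coding genes alone 19, and a mean CPM of at least 5 kept 18, with 3 calls lost and too few epithelial markers left to test. Leaving out genes with a shifted word in the fit with pairs kept 19. An estimated correlation called 0 lists (0 also with the block), and fry called 3 (17 with the block). Medians of called lists reversed without siUAP1 replicate 1. With 1 library left out the G1/S list ranged from -0.244 to 0.0223, the G2/M list from -0.228 to 0.00185, the NF-kB list from -0.0251 to 0.345, the cholesterol list from -0.0114 to 0.387 and the mesenchymal list from -0.0233 to 0.188. All 22 lists kept their calls with the block, also with any pair left out; beyond the counts of genes and the named genes given with it, the block changed no other camera call at the preset correlation than those of the 3 lists named in the report. Of named genes and settings, 2956 values stayed on their side of the threshold, 1378 gained and 141 lost a call, and none changed sign with a call. Of 148 named genes called with the block, 9, 13 and 33 lost the call without pair 1, 2 and 3. In the simulation, which kept the differences between pairs, the fit without pairs missed most changes of 1.5-fold (23.9% recovered). The blocked fit recovered 95.5% of them at the same depths.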

Other observations

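The tests of gene families, of microRNA sites, of microRNA-29, of words within single pairs, of gene length and GC, of lists with the pairs at an estimated correlation and of lists without genes holding a shifted word were chosen only after the result was seen. Families are protein-coding genes sharing the opening words of their names, or other genes sharing an annotated gene type. The members named were chosen after their values were seen. Of 109 families of at least 15 tested genes, camera in the fit with pairs called 3, all higher in siUAP1 libraries. Each lost the call with an estimated correlation (adjusted p = 0.983), and fry called 0 of these 3 (adjusted p = 0.0972, 0.0972 and 0.103). Of 22 integrin subunit genes, 10 rose and 1 fell (adjusted p = 8.05e-12), including ITGA4 (log2 fold change 0.62, SE 0.0565) and ITGA3 (0.51, SE 0.0466). Of 28 collagen genes, 11 rose and 2 fell (adjusted p = 4.4e-07), and the basement membrane genes COL4A1 (0.66, SE 0.0517) and COL4A2 (0.65, SE 0.0479) and the fibrillar genes COL1A1 (0.85, SE 0.0546) and COL5A2 (0.42, SE 0.0521) were among those that rose. Of 35 protein tyrosine phosphatase and kinase genes, 10 rose and 0 fell (adjusted p = 0.00454), by smaller amounts, such as PTPRE (0.39, SE 0.0852), PTPRJ (0.33, SE 0.0654) and PTPRS (0.29, SE 0.0501). The 3' UTRs of COL1A1 and PTPRE hold an upward word and that of COL4A2 words of both kinds. The 224 solute carrier genes, with 37 higher and 6 lower, were not called as a family (adjusted p = 0.145).

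Other splits of the 6 libraries bear on both counts of changed genes. The real split gave 17 genes and each of the other splits of the 10 gave 0, so that 1 of 10 gave as many. Within pairs the real split gave 2556 and the other splits of the 4 gave 0 each, so that 1 of 4 gave as many. With so few splits no share under 0.05 was possible.

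Genes that fell with the pairs carried certain 3' UTR words more often than other genes. The strongest downward word of 16318 was AAACGAA (z = -9.14). It was also the strongest in each pair alone (z = -5.62, -8.76 and -10.3 in pairs 1 to 3), so that the word chosen in any 1 pair was shifted in the other 2. Of 1019 fallen genes 267 (26.2%) held at least 1 of the 5 downward words, against 10.4% of other genes. The words were chosen by the same fold changes, so these shares, and those of upward words below, partly restate that choice and give no size for the effect. Within the longer word AAAACGAA it occurs 2 times in UAP1, in coding sequence of exon 5 or 6 of protein-coding transcripts, at chromosome 1, 162587484 to 162587491 and 162587579 to 162587586, as a UAP1 siRNA's seed match would have to, whereas 17.8% of all words occur in a UAP1 transcript. A candidate explanation is therefore that part of the falls, such as those of LCLAT1, ETV5, MAGT1 and SKI, came from partial matches to a UAP1 siRNA rather than from loss of UAP1. Words in no UAP1 transcript, such as AATCGAA (z = -6.71), were shifted too, most fallen genes hold none, and an effect of UAP1 loss itself stays open and untested, since every siUAP1 library received the siRNAs.

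The strongest upward word was GCAACCA (z = 9.52, and 9.92, 8.19 and 7.05 in pairs 1 to 3), with AGCAACC (9.02), the strongest in pair 3 alone, and TGCAACC (5.47), and 448 of 1232 risen genes (36.4%) held an upward word against 19.7% of other genes. Because a siRNA in the control libraries would lower its own partial matches there, a candidate explanation for part of the rises, including NUCKS1, LMLN and TIMP3, is the seed of the control siRNA. Relief of endogenous microRNA sites by the transfected siRNAs cannot be told apart from no such relief: the median z over 16 microRNA families was 0.224 (95% bootstrap interval -0.543 to 1.32), too wide to place it below 1. Among these families the microRNA-29 site TGGTGCT had the highest z (3.8, short of the bound of 4.5) and the let-7 site the lowest (-1.91). The z was above 0 for 10 of the 16. The rises of MMP2, TGFBI and TINAGL1, which hold no upward word, and an effect of UAP1 loss stay open.

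The collagen and matrix list had a median of 0.342 with the pairs (95% bootstrap interval 0.218 to 0.449). Intervals in this paragraph come from resampling list members, taken as independent, and do not measure the spread between pairs. Taking out each library's trend on gene length and GC did not remove the rise (median 0.334, camera adjusted p = 9.76e-30, or adjusted p = 0.176 with an estimated correlation). Leaving out genes that hold a shifted word did not either (median 0.309 over 33 members, interval 0.194 to 0.448, camera adjusted p = 5.44e-26, or adjusted p = 0.169 with an estimated correlation). These values argue against such trends, or the shifted words in the members' longest annotated 3' UTRs, as the whole cause of the shift. Genes holding only words short of the bound, such as GCAACCT (z = 4.13), were not left out, and other 3' UTRs were not searched. The values do not bear on effects of the siRNAs that reach the list through other genes. Before either step the list was likewise not called by camera with an estimated correlation (adjusted p = 0.171). RNA of fibroblasts is argued against by DCN and LUM, abundant in fibroblasts, which reached at most 0.166 CPM in any siUAP1 library, while COL1A1 and SPARC rose (0.85 and 0.58) from a high level in control libraries. A contribution of microRNA-29 sites could not be decided: the 18 members with a site had a median of 0.413 and the 25 without one 0.264 (interval 0.0358 to 0.449, permutation p = 0.187, two-sided, 100000 resamples). Without genes holding a shifted word, 3 other lists lost their calls with the pairs. The YAP and TEAD median went from 0.197 (25 members, interval 0.0509 to 0.281) to 0.0586 (17 members, -0.0893 to 0.282, adjusted p = 0.0679) and the p53 median from 0.0728 (34 members, -0.00289 to 0.217) to 0.045 (20 members, -0.012 to 0.24, adjusted p = 0.129). The Golgi median stayed about as large, 0.12 (23 members, -0.0119 to 0.165) and 0.107 (17 members, -0.0253 to 0.139, adjusted p = 0.176). These intervals overlap and fewer members were tested, so the lost calls do not show the words to be the cause. An effect of UAP1 loss on matrix genes stays open as a hypothesis, untested against the siRNAs' other effects.

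The non-coding AL596244.1 (chromosome 9, 121815674 to 121819452, minus strand) lies 2475 bases beyond the annotated end of TTLL11 on the same strand, and both were lower (-1.64 and -1.03). Its 3779-base transcript holds AAACGAA 2 times, whereas the 3' UTR searched for TTLL11, the longest annotated, holds no downward word. Whether the 2 belong to a longer transcript was not tested. LINC02376 holds none of the downward words.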
